A study of Mus musculus with 288 samples.

How the data were processed

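Gene expression and transcription factor reporters were measured in bone marrow-derived macrophages (BMDMs) of C57BL/6 mice, grown with M-CSF over 7 days. Cells were treated for 24 h with DMSO (the solvent control), dCA at 100 nM or BRD-6989 at 1 µM, both given by the labels as CDK8 inhibitors. They were then left without a stimulus (NoStim) or given 1 of 11 stimuli, named here as in the labels, and collected at 8 times from 15 to 180 min. The series text gives 0 to 4 h; the times of the sample labels were used. This gave 288 wells, with 1 well for each pretreatment, stimulus and time. Each pretreatment filled 1 plate with its own library index, so inhibitor and plate cannot be told apart, and the labels give no separate cultures or animals.

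Genes were read by 3' digital gene expression, with a 10-base random barcode and a 6-base well tag in the primer. The authors deposited counts of distinct barcodes (UMI) and total read counts for 23481 genes, of which 8773 had no UMI in any well. TF-seq, an assay in which each reporter construct is read through its own sequence tag, gave deposited counts for 58 reporters. The deposited file of normalized reporter values was identical to the reporter counts and was not used. BWA, edgeR and mm10 are named per the submitters' processing notes; versions, the annotation, the counting steps and how the reporters entered the cells are not given in the sources used here. Symbols are those of the deposited tables, and coordinates come from a reference annotation of GRCm38.p6 (mm10).

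UMI totals per well ran from 37542 to 127223 with a median of 77485, read totals from 206236 to 836144, and 3840 to 6761 genes were detected per well. Rn45s, the 45S ribosomal RNA precursor, took 49.15% of all UMI, which left 21810 to 70797 UMI per well for other genes. Reporter totals per well ran from 716 to 8354. No well fell under 0.1 of the median UMI total, and 0 wells were left out. Intervals given for low counts are exact 95% Poisson or conditional binomial intervals and cover counting error only. Where a group had 0 UMI, its bound was set at 3 counts over the whole group.

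Analyses used R 4.3.3, data.table (version 1.17.8), edgeR 4.0.16 (TMM normalization and quasi-likelihood tests), limma 3.58.1 for gene list tests and DESeq2 1.42.0 as an alternative. Tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. For effects over all conditions, the 8 times of each pretreatment and stimulus were summed into 36 libraries of 515816 to 746625 UMI. Genes passed filterByExpr with a minimum count of 10, and the 12 stimulus conditions entered as blocks; the replicate block changed the number of genes called between dCA and BRD-6989, which was 75 without it. Unstimulated wells (8 per pretreatment) were compared with time as a block, in genes with a mean of at least 1 UMI per well. Stimuli were compared with NoStim in the 60 DMSO wells of 60 min and later, with time as a covariate. The inhibitors' effects on the response were tested in the 180 wells of the same times, as the mean over 11 stimuli and as an 11-df test of any difference between conditions. Reporters were tested in the same designs. Every p-value of a gene or reporter measures the spread between wells, or between libraries summed from them. A camera p-value of a gene list sets its genes against the other genes, at a preset correlation between genes. No p-value measures the spread between cultures or animals.

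A total of 31 gene lists (592 genes) for macrophage, metabolic and stress pathways and for markers of other cell types was written down. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, and again with a correlation estimated per list and with fry. The groups, tests, lists, thresholds and most alternatives were set before the data were examined. So was the rule for naming genes. It takes the 8 largest rises and falls per inhibitor over all conditions with a mean of at least 20 CPM and the direction in at least 10 of 12 conditions, and the 4 largest each way between inhibitors. It takes the 5 largest each way in unstimulated wells at a mean of at least 2 UMI, the 3 largest rises and the largest fall per stimulus, the 5 smallest p of each 11-df test, and up to 2 members each way per list. It takes up to 6 reporters per comparison and a fixed set: Il10, Tnf, Il1b, Il6, Il12b, Cxcl10, Ifit1, Nfkbiz, Fos, Jun, Egr1, Cdk8, Cdk19, Ccnc, Med12 and Med13. Mitochondrial, predicted and Riken-named genes were replaced by the next gene.

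The tests were tried on simulated data with the dispersion trend of the unstimulated wells. Over all conditions, 72 of 94 genes changed 2-fold and 93 of 93 changed 4-fold were recovered, with 10 of 5452 unchanged genes called. In unstimulated wells, 1 of 94 and 15 of 86 were recovered. For a stimulus in DMSO the numbers were 2 of 95 and 4 of 95. For the effect on the response they were 0 of 97 and 8 of 93, and for its 11-df test 0 of 97 and 15 of 98. Changed reporters were recovered in 6 of 6 and 5 of 5. An earlier simulation with 1 dispersion for all genes recovered 86 of 96 and 96 of 96 over all conditions, 4 of 99 of the 4-fold changes in the 11-df test, and 0 in the unstimulated, stimulus and mean response tests. Tests on single wells therefore missed most of the simulated changes. Their counts are not lower limits, since random regroupings of the unstimulated wells called up to 12 genes for dCA and 21 for BRD-6989.

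Alternatives were DESeq2 size factors, the DESeq2 Wald test, looser and stricter count filters, total read counts in place of UMI, no replicate block, single wells in place of sums, thinned counts, late or all times, deeper wells, and leaving out 1 condition or time at once. The inhibitor effects over all conditions were also fitted with the Rn45s share of each library as a covariate. Leaving out Rn45s, leaving out wells under 0.5 of the median UMI total in the stimulus tests, and scaling reporters by the UMI total without Rn45s were chosen after seeing the data. No DMSO well fell under 0.5 of the median (lowest 43788), so leaving out such wells changed nothing in the stimulus tests.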

Results

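Counts came from mouse bone marrow-derived macrophages, 96 wells for each pretreatment (DMSO, dCA and BRD-6989), with 8 wells per pretreatment and stimulus. UMI totals per well ran from 43788 to 123855 in DMSO, from 41118 to 114906 in dCA and from 37542 to 127223 in BRD-6989. Rn45s took 52.7% ± 6.88 of the UMI in DMSO, 49.0% ± 7.04 in dCA and 43.6% ± 6.75 in BRD-6989 (mean ± SD, n = 96 wells each). Log2 changes below are given ± SE, and expression levels in CPM (UMI per 1e6 UMI, TMM-scaled) are means ± SD over the 12 summed libraries of a pretreatment unless another n is stated.

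What dCA did to gene expression whether or not the cells were stimulated was read from the 12 matched conditions. The lysosomal protease Ctsl (chromosome 13, 64361890 to 64370772, GRCm38.p6 (mm10)) rose from 406 ± 36.5 CPM in DMSO to 2698 ± 212 CPM in dCA, a log2 change of 2.73 ± 0.04 (adjusted p = 1.51e-48). Nptx1, a neuronal pentraxin (chromosome 11, 119538719 to 119547820), rose from 16.04 ± 12.9 to 197 ± 44.4 CPM. Ifit3, an interferon-induced gene (chromosome 19, 34583119 to 34588982), dropped from 92.1 ± 55.9 to 33.2 ± 22.2 CPM. In edgeR, 1023 of 5712 genes passed the threshold, 455 of them lower and the others higher under dCA. With the Rn45s share of each library as a covariate 604 passed. Among genes with a mean of at least 20 CPM, the largest rises besides Ctsl and Nptx1 (3.63 ± 0.22) were Ctla2a at 3.63 ± 0.20, the chemokine receptor Ccr3 at 3.63 ± 0.28, the myo-inositol transporter Slc5a3 at 2.78 ± 0.26, Akap2 at 2.72 ± 0.17, the chemokine Ccl8 at 2.50 ± 0.40 and Cdk20 at 2.43 ± 0.23. Among the largest falls were Emb at -2.37 ± 0.27, Spn (CD43) at -1.91 ± 0.36, Irg1 (itaconate synthesis) at -1.85 ± 0.24, AB124611 at -1.83 ± 0.31, Cmah at -1.81 ± 0.28, Pira4 at -1.62 ± 0.31 and Arl5c at -1.59 ± 0.23. Each of these genes moved in its direction in 11 or 12 of the 12 conditions. Among the genes fixed in advance, Il1b fell by 1.32 ± 0.18, Cxcl10 fell by 1.00 ± 0.10, Egr1 fell by 1.59 ± 0.27, Fos fell by 1.39 ± 0.34, Jun fell by 0.46 ± 0.12, Il12b fell by 0.86 ± 0.27 and Nfkbiz fell by 0.31 ± 0.10. Tnf at -0.32 ± 0.13 (adjusted p = 0.080, lower in 9 of 12 conditions) and Ifit1 at -0.29 ± 0.13 (adjusted p = 0.117, lower in 7 of 12) missed the threshold. With total read counts the calls of Spn (adjusted p = 0.0588), Il12b (0.188) and Nfkbiz (0.146) ended, with their log2 values at -1.63, -0.96 and -0.30. The Il12b call also ended without NoStim (0.0558), and that of Nfkbiz without LPS (0.0542), Poly(I:C) (0.0561), FLA (0.0684) or TDB (0.0680). Wells of 60 min and later also ended both (0.113 for Il12b and 0.0552 for Nfkbiz), while the stricter filter left 322 genes called.

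Under dCA, cholesterol synthesis genes rose and interferon genes fell. Of 21 cholesterol synthesis genes, 12 rose and 0 fell, or 14 and 0 adjusted over the list alone, with Hmgcs1 at 1.14 ± 0.15 and Idi1 at 0.99 ± 0.15 (median 0.65, adjusted p = 6.71e-08). Of 46 interferon response genes, 18 fell, among them Ifit2 at -1.03 ± 0.14, and Ly6e rose at 0.37 ± 0.06, or 23 and 1 adjusted over the list alone (median -0.36, adjusted p = 1.93e-07). With the Rn45s share as a covariate 8 of the 46 fell past the threshold, with a median of -0.37. Of 12 genes of interferon-gamma response and antigen processing, 6 fell and 0 rose, or 10 and 0 adjusted over the list alone, with the immunoproteasome genes Psmb8 at -0.75 ± 0.13 and Psme2 at -0.52 ± 0.11 (median -0.48, adjusted p = 1.14e-05). Of 16 genes of LXR targets and lipid handling, 8 rose and 3 fell, the same numbers adjusted over the list alone, with the scavenger receptor Cd36 at 1.23 ± 0.08, the lipase Lpl at 0.71 ± 0.05, Apoe at -0.73 ± 0.15 and Pltp at -0.61 ± 0.12 (median 0.65, adjusted p = 0.000447). Of 23 glycolysis and hypoxia genes, 7 fell and 2 rose, or 11 and 2 adjusted over the list alone, with Gapdh at -0.36 ± 0.04, Ldha at -0.50 ± 0.05 and Pgam1 at 0.34 ± 0.09 (median -0.23, adjusted p = 0.00122). Of 30 cell cycle genes, 8 fell and 1 rose, or 11 and 1 adjusted over the list alone, with Hmgb2 at -0.75 ± 0.11, Mki67 at -0.53 ± 0.10 and Pcna at 0.72 ± 0.11 (median -0.28, adjusted p = 0.00114). Of 10 genes of the NRF2 oxidative stress list, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone, led by Fth1 (iron storage) at 0.78 ± 0.02 and Slc48a1 (heme transport) at 1.05 ± 0.12 (median 0.14, adjusted p = 0.0113). Of 26 lysosome genes, 9 rose and 0 fell, or 9 and 1 adjusted over the list alone, with Ctsl and Ctsd at 0.78 ± 0.04 in the lead; the median of -0.01 lies below 0, while the mean of 0.27 and the test point up (adjusted p = 0.00820). Of the list of osteoclast markers, Atp6v0d2 rose by 2.31 ± 0.25 and Itgb3 by 3.04 ± 0.52. Of 38 genes of the NF-kB inflammatory response, 15 fell and 5 rose, or 19 and 5 adjusted over the list alone, with Il1b, the chemokine Ccl3 at -0.70 ± 0.10, Ccl7 at 0.60 ± 0.06 and Bcl2a1b at 1.11 ± 0.16 (median -0.36, adjusted p = 0.00247). This call was lost at adjusted p = 0.0976 with an estimated correlation. Of 22 immediate early and AP-1 genes, 10 fell and 4 rose, or 11 and 4 adjusted over the list alone, with Junb at -0.67 ± 0.10, Egr2 at 1.30 ± 0.27 and Myc at 0.70 ± 0.17 (median -0.38, adjusted p = 0.00587), and here adjusted p = 0.0691 with an estimated correlation. Of 31 nuclear genes of oxidative phosphorylation, 4 rose, or 2 adjusted over the list alone, with Ndufa1 at 0.59 ± 0.11 and Ndufv2 at 0.74 ± 0.21 (median 0.12, adjusted p = 0.0441), and adjusted p = 0.166 with an estimated correlation. The other dCA calls above held with an estimated correlation. In random regroupings of the libraries the preset correlation also called up to 11 lists, and more in another set of draws, against 21 here for both inhibitors together.

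BRD-6989 was asked the same question over the same 12 conditions. Ctsl rose to 2352 ± 178 CPM, a log2 change of 2.54 ± 0.04, and Nptx1 to 179 ± 40.0 CPM, a change of 3.50 ± 0.22. Ifit3 dropped to 15.5 ± 12.0 CPM, a change of -2.60 ± 0.23. Irf7, a transcription factor of the interferon response (chromosome 7, 141263183 to 141266499), dropped from 129 ± 37.8 CPM in DMSO to 37.3 ± 20.6 CPM, a change of -1.84 ± 0.16 (adjusted p = 1.69e-13, lower in 12 of 12 conditions). In edgeR, 1195 of 5712 genes passed the threshold, 595 higher and 600 lower. With the Rn45s share as a covariate 191 passed. Further large rises were Ctla2a at 3.13 ± 0.21, Ccr3 at 3.04 ± 0.28, Akap2 at 2.95 ± 0.16, Slc5a3 at 2.82 ± 0.26, Nanos1 at 2.73 ± 0.21 and the transferrin receptor Tfrc at 2.43 ± 0.22. Further large falls were Slfn4 at -2.25 ± 0.31, Isg20 at -2.03 ± 0.39, the sialic acid receptor Siglec1 at -1.85 ± 0.24, the near-identical interferon-induced GTPases Tgtp1 at -1.83 ± 0.28 and Tgtp2 at -1.80 ± 0.29, and Spn at -1.79 ± 0.35. All of these kept their direction in at least 10 of 12 conditions, which the rule for naming genes required. Of the genes fixed in advance, Cxcl10 fell by 1.10 ± 0.09, Egr1 fell by 1.15 ± 0.25, Il1b fell by 0.93 ± 0.17, Ifit1 fell by 0.72 ± 0.13, Tnf fell by 0.42 ± 0.13, Nfkbiz fell by 0.34 ± 0.10 and Med12 fell by 1.02 ± 0.26. Jun at -0.29 ± 0.12 (adjusted p = 0.073, lower in 10 of 12 conditions), Il12b at -0.57 ± 0.26 (0.128, lower in 8) and Fos at -0.26 ± 0.31 (0.631, lower in 6) missed the threshold. The Spn call ended with total read counts (-1.49, adjusted p = 0.0865) and that of Tnf with wells of 60 min and later (-0.31, adjusted p = 0.119). Those wells alone called 779 genes, and the stricter filter 325.

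Under BRD-6989, 34 of 46 interferon response genes fell and 0 rose, or 37 and 0 adjusted over the list alone, with Ifit2 at -1.71 ± 0.14 and Ifit3 (median -1.02, adjusted p = 5.55e-21). Of 12 genes of interferon-gamma response and antigen processing, 10 fell and 0 rose, or 12 and 0 adjusted over the list alone, with Psmb8 at -0.94 ± 0.13 and H2-K1 at -0.56 ± 0.07 (median -0.63, adjusted p = 3.38e-09). The Rn45s share was lower in the BRD-6989 wells than in the DMSO wells, as given above. With it as a covariate 9 of the 46 interferon response genes fell past the threshold, with a median of -0.83. Of 21 cholesterol synthesis genes, 14 rose and 0 fell, or 15 and 0 adjusted over the list alone, with Idi1 at 1.35 ± 0.15 and Hmgcs1 at 1.32 ± 0.15 (median 0.92, adjusted p = 2.78e-09). Of 16 genes of LXR targets and lipid handling, 8 rose and 3 fell, the same numbers adjusted over the list alone, with Cd36 at 1.48 ± 0.08, Lpl at 0.90 ± 0.05, Apoe at -0.91 ± 0.15 and Pltp at -0.54 ± 0.12 (median 0.43, adjusted p = 0.000397). Of 10 genes of the NRF2 oxidative stress list, 6 rose and 0 fell, or 8 and 0 adjusted over the list alone, with Fth1 at 0.73 ± 0.02 and the peroxiredoxin Prdx1 at 0.64 ± 0.06 (median 0.57, adjusted p = 2.90e-05). Of 23 glycolysis and hypoxia genes, 11 fell and 2 rose, or 12 and 2 adjusted over the list alone, with Aldoa at -0.68 ± 0.06, Gapdh at -0.46 ± 0.04, Pgam1 at 0.46 ± 0.08 and Pgk1 at 0.28 ± 0.08 (median -0.33, adjusted p = 0.000144). Of 30 cell cycle genes, 7 fell and 1 rose, or 8 and 1 adjusted over the list alone, with Ccnd2 at -1.05 ± 0.15, Mcm7 at -0.85 ± 0.25 and Pcna at 0.94 ± 0.11 (median -0.20, adjusted p = 0.0203). Of 16 genes of the unfolded protein and integrated stress response, 5 rose and 1 fell, the same adjusted over the list alone, with Asns at 1.12 ± 0.26, Atf4 at 0.60 ± 0.13 and Pdia4 at -0.50 ± 0.18 (median 0.26, adjusted p = 0.0253), and the call ended with total read counts (adjusted p = 0.0914). Of 38 genes of the NF-kB inflammatory response, 16 fell and 7 rose, or 17 and 8 adjusted over the list alone, with Icam1 at -0.87 ± 0.13, Birc3 at -0.77 ± 0.13, Bcl2a1b at 1.21 ± 0.15 and Ccl7 at 0.38 ± 0.06 (median -0.33, adjusted p = 0.0148), and adjusted p = 0.178 with an estimated correlation. Of 19 macrophage identity genes, 9 fell and 5 rose, the same adjusted over the list alone, with the complement gene C1qb at -0.46 ± 0.05, Emilin2 at -1.52 ± 0.16, the mannose receptor Mrc1 at 0.43 ± 0.05 and Clec4d at 0.67 ± 0.10 (median -0.10, adjusted p = 0.0451), and adjusted p = 0.0691 with an estimated correlation. The other BRD-6989 calls above held with an estimated correlation.

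**Figure D1:**
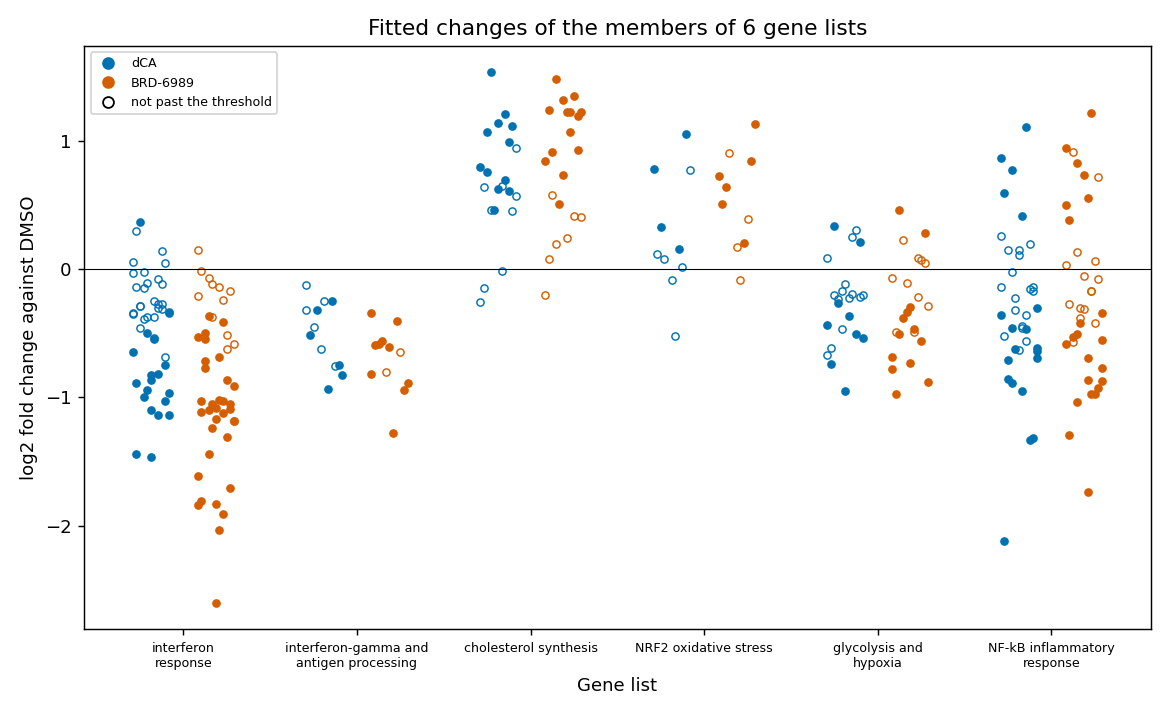
Log2 change against DMSO over all conditions (vertical axis) of each member of 6 gene lists under dCA and BRD-6989; 1 point per gene, filled where the gene passed the threshold. Interferon response genes lie mostly below 0, with medians of -0.36 and -1.02, and cholesterol synthesis genes mostly above, with medians of 0.65 and 0.92.

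How far the inhibitors shared their effects was asked gene by gene. Of 5712 genes, 416 were higher under both, 309 were lower under both, and 6 were called in opposite directions. Independent calls would share 59.2 and 47.8. Both sets of calls use the same DMSO libraries of 1 plate, so they are not independent, and those numbers are no chance level. Ly6a at 0.53 ± 0.15 under dCA and -0.86 ± 0.16 under BRD-6989, and Ly6e at 0.37 ± 0.06 and -0.50 ± 0.06, were among the opposite calls. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.792. In simulated unchanged groups r was 0.0306 on average (0.0084 to 0.0693 over 20 draws). Those groups were drawn around the fitted values of the DMSO libraries they were compared with. The noise of these libraries could not enter, so the simulated r does not show what sharing them gives. With the effects taken from different conditions, 6 each, r was 0.516 and 0.510, with the DMSO plate still common to both effects.

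**Figure D2:**
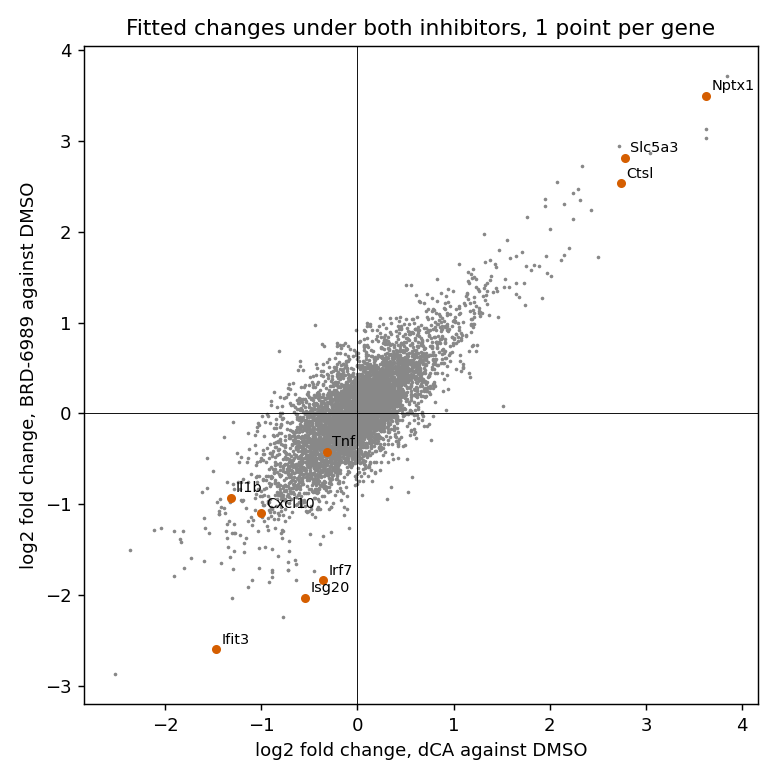
Log2 change against DMSO over all conditions under dCA (horizontal axis) and BRD-6989 (vertical axis), 1 point per gene for 5712 genes, with some genes of the report named. The changes correlated at r = 0.792, and Irf7 and Ifit3 lie lower on the BRD-6989 axis than on the dCA axis.

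The direct comparison of dCA at 100 nM with BRD-6989 at 1 µM asked where the inhibitors differed; the doses differ, so these are values side by side. Irf7, Ly6a, Slfn4 and Isg20, which interferon induces, were higher under dCA than under BRD-6989. Irf7 differed by 1.48 ± 0.17 (adjusted p = 3.35e-09, higher in 12 of 12 conditions), Ly6a by 1.39 ± 0.15 (116 ± 35.3 against 45.5 ± 23.7 CPM), Slfn4 by 1.48 ± 0.32 and Isg20 by 1.49 ± 0.40. Lower under dCA were the condensin gene Smc2 at -1.04 ± 0.17, the kinetochore motor gene Cenpe at -1.03 ± 0.17, Leprot at -1.11 ± 0.25 and Arhgap6 at -0.91 ± 0.27. Nptx1 (0.12 ± 0.17) and Slc5a3 (-0.04 ± 0.21) did not pass the threshold, while Ctsl was higher under dCA by 0.20 ± 0.04 and Ctsd by 0.27 ± 0.04. In all, 198 of 5712 genes passed in edgeR, 134 higher and 64 lower under dCA; total read counts gave 84, late wells 82 and a fit without the replicate block 75. With single wells as units the median over all genes moved from -0.0063 to -0.15, 276 genes passed and 21.0% of them were higher under dCA in place of 67.7%. The balance of directions thus depends on whether wells were summed, which also changes the TMM scaling. The differences of Ctsl and Ctsd are of the order of that shift, so their size can depend on it. Isg20 and Arhgap6 lost their calls with read counts, and also without NoStim (adjusted p = 0.0698 and 0.0673), Poly(I:C) (0.0663 and 0.150) or SeV (0.0514 and 0.0583), and Arhgap6 without R848 (0.0640), FLA (0.0918), Zymosan (0.104), TDB (0.106) or MDP (0.0810). Slfn4 (adjusted p = 0.0537) and Leprot (0.0937) lost theirs with read counts, Slfn4 (0.179) and Arhgap6 (0.154) with late wells, Arhgap6 with thinned counts (0.0583), and Isg20 (0.312) and Arhgap6 (0.152) without the block.

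In unstimulated cells, 8 wells per pretreatment showed the inhibitor effects without any ligand. Slc5a3 had 54 UMI under dCA and 46 under BRD-6989 against 0 in DMSO, at least 16.7-fold and at least 12.8-fold higher against a floor of 3 counts over the group. Ctla2a had 76 and 67 UMI against 2, ratios of 35.2 (95% counting interval 9.42 to 296) and 27.9 (7.42 to 235). Nptx1 rose by 4.20 ± 0.57 under dCA and 3.66 ± 0.57 under BRD-6989, higher in 8 of 8 times in both. Ctsl, singled out here after its values were seen, rose by 2.72 ± 0.13 and 2.53 ± 0.13. Under dCA, Ccr3 had 39 UMI against 1 (ratio 36.1, 6.11 to 1463) and Tfrc rose by 3.59 ± 0.78. The RNA sensor gene Ddx58 fell by 2.93 ± 0.66, the cyclin gene Ccnd2 fell by 1.83 ± 0.48, Psmd7 fell by 1.57 ± 0.41, Sppl2a fell by 1.54 ± 0.44 and S100a4 fell by 0.71 ± 0.14. Under BRD-6989, Gadd45a had 37 UMI against 1 (ratio 30.8, 5.19 to 1248) and Rapgef5 34 against 1 (ratio 28.3, 4.74 to 1149). Ifit2 fell by 2.90 ± 0.55, Ppp1r18 fell by 2.52 ± 0.64, Ccnd2 fell by 2.46 ± 0.49, Plxnb2 fell by 2.22 ± 0.48 and Pld4 fell by 1.85 ± 0.46. Cxcl10 fell by 1.44 ± 0.28 under BRD-6989 (adjusted p = 0.000125, lower in 7 of 8 times), and under dCA it stood at -0.94 ± 0.28 (adjusted p = 0.066, lower in 7 of 8). Of 5835 genes tested in edgeR, 58 passed under dCA (47 higher, 11 lower) and 66 under BRD-6989 (45 higher, 21 lower). Total read counts gave 28 and 30, where Ccnd2 (both inhibitors), Psmd7, Sppl2a, S100a4, Plxnb2, Pld4 and Cxcl10 were not called. Leaving out 1 time ended the calls of Ccr3 (without 30, 45 or 60 min), Ccnd2 under dCA (45, 90 or 150), Psmd7 (15, 45, 60, 150 or 180), Sppl2a (15, 60, 90, 120, 150 or 180), Gadd45a (30, 45, 60, 90, 150 or 180), Rapgef5 (all but 150), Ppp1r18 (15, 45 or 120) and Pld4 (15 or 90).

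What each stimulus did without an inhibitor was read from 5 DMSO wells of 60 to 180 min against 5 NoStim wells. LPS raised the interferon-induced gene Ifit1 from 28.4 ± 15.4 to 1288 ± 745 CPM (5.43 ± 0.79 on the log2 scale) and the cytokine Il1b from 23.0 ± 32.0 to 467 ± 260 CPM (4.14 ± 0.91; mean ± SD, n = 5). With MDP_LPS these changes were 5.28 ± 0.78 and 4.72 ± 0.91, and the chemokine Ccl5 had 317 UMI against 3 (ratio 95.1, 32.2 to 464). Zymosan raised Ifit1 by 4.15 ± 0.79 and Il1b by 3.75 ± 0.91, and Poly(I:C) raised Ifit1 by 4.68 ± 0.78 while Il1b stood at 0.91 ± 1.00. Tnfaip2, an NF-kB target (chromosome 12, 111442450 to 111455018), rose by 3.61 ± 0.30 with CpG, 3.39 ± 0.30 with FLA, 2.09 ± 0.30 with MDP and 1.59 ± 0.30 with TDB, higher in 5 of 5 wells each time. Nfkbiz rose with LPS (2.78 ± 0.61), MDP_LPS (2.80 ± 0.60), Pam3cys (2.63 ± 0.61), CpG (2.78 ± 0.61), R848 (2.93 ± 0.61) and Zymosan (2.44 ± 0.60). Tnf rose by 1.88 ± 0.52 with LPS (adjusted p = 0.0487, higher in 4 of 5 wells), 1.97 ± 0.52 with MDP_LPS and 2.10 ± 0.52 with R848, Il1b also with R848 (3.56 ± 0.91, adjusted p = 0.0499), and Cxcl10 with LPS (1.79 ± 0.42) and MDP_LPS (1.77 ± 0.42).

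Genes not seen in NoStim wells gave lower bounds. With LPS, Dusp2 was at least 16.03-fold and AW112010 at least 18.3-fold higher. AW112010 was at least 17.1-fold and Edn1 at least 12.3-fold higher with MDP_LPS. Saa3, an acute phase gene, was at least 18.9-fold higher with Pam3cys and 13.4-fold with R848, where Cp was at least 13.7-fold higher. Saa3 varied widely between wells, at 143 ± 197 CPM with Pam3cys and 121 ± 192 CPM with R848 (mean ± SD). Its adjusted p with R848 in edgeR was 0.0499. Poly(I:C) gave at least 11.8-fold for Cd69 and 9.76-fold for Ccrl2, and Zymosan at least 13.4-fold for Cd69 and 10.7-fold for AW112010. The neutrophil chemokine Cxcl1 had 1 UMI in NoStim and 65 with Pam3cys (ratio 68.2, 11.8 to 2733), 86 with Zymosan (84.0, 14.7 to 3357), 51 with R848 (49.9, 8.56 to 2008) and 25 with CpG (33.3, 5.46 to 1369). With CpG the edgeR adjusted p of Cxcl1 was 0.0499. Ccl5 had 3 UMI in NoStim, 184 with Poly(I:C) (ratio 47.3, 15.9 to 231) and 58 with CpG (25.8, 8.40 to 129). Cxcl2 rose by 4.61 ± 0.84 with Pam3cys, Gadd45b by 3.81 ± 0.66 and Ehd1 by 3.02 ± 0.47 with FLA, the antiviral gene Rsad2 by 2.99 ± 0.57 and Ccl4 by 2.57 ± 0.43 with SeV, and Nfkbia by 1.79 ± 0.31 and Mtdh by 1.26 ± 0.29 with MDP. The transcription factor Maf fell by 1.24 ± 0.30 with CpG, 1.20 ± 0.29 with R848 (each as log2) and 1.36 ± 0.29 with Zymosan, and Smc1a fell by 1.61 ± 0.42 with Pam3cys. Srsf2 had 2 UMI with LPS against 54 (ratio 0.0424, 0.0050 to 0.161). Fam89b had 0 with MDP_LPS against 19, at least 7.04-fold lower, and Sptlc1 0 with Poly(I:C) against 27, at least 11.7-fold lower.

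Of 37 NF-kB inflammatory genes, 16 rose with MDP_LPS, 15 with LPS, 13 each with Pam3cys and R848, 11 with Zymosan, 7 each with CpG and Poly(I:C), 4 with FLA, 2 with MDP and 1 each with SeV and TDB, and 0 fell with any stimulus. Adjusted over the list alone these numbers were 28, 25, 22, 22, 24, 18, 14, 16, 5, 7 and 8. Of 47 interferon response genes, 6 each rose with LPS and MDP_LPS, 5 with Zymosan, 4 with Poly(I:C) and 1 each with Pam3cys and SeV, or 11, 16, 7, 5, 1 and 4 adjusted over the list alone; with CpG, R848, FLA, TDB and MDP edgeR called 0 over all genes, and 1 (MDP) or 0 adjusted over the list alone. Of 19 immediate early genes, 3 each rose with LPS and MDP_LPS, 2 each with Pam3cys, CpG, R848 and Zymosan, 1 each with Poly(I:C) and FLA, and 0 with SeV, TDB and MDP, or 4, 6, 3, 3, 4, 5, 2, 2, 0, 1 and 1 adjusted over the list alone. In edgeR, 61 of 5516 genes passed with LPS, 61 with MDP_LPS, 32 with R848, 32 with Zymosan, 31 with Poly(I:C), 26 with Pam3cys, 15 with CpG, 12 with FLA, 4 with MDP, 2 with SeV and 1 with TDB. Differences between stimuli were not tested gene by gene, and read counts lowered most numbers, as did leaving out times: MDP_LPS fell to 36 without 1 time, R848 to 20, Pam3cys to 15 and Poly(I:C) to 16, and the SeV and TDB calls reached 0. The Tnf call with LPS ended with read counts and without 60, 90, 120 or 150 min.

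Whether an inhibitor changed the response to stimulation itself was asked in 180 wells. In edgeR, 0 of 5772 genes passed for the mean over 11 stimuli, with 325 at an unadjusted p under 0.05 for dCA and 261 for BRD-6989 (lowest adjusted p 0.516 and 0.453), and DESeq2 size factors in the same test also gave 0. The test of any difference between conditions gave 0 as well, with 573 and 394 at an unadjusted p under 0.05. Its smallest p-values were those of Gadd45a (3.82e-05), Atp6v0d2 (9.87e-05), Ulk2 (0.000106), Tnrc18 (0.000225) and Svil (0.000314) for dCA, and Ptgs2 (0.000263), Eci1 (0.000368), Hibch, Adam17 and Ednrb for BRD-6989; none passed. Of 19 gene lists tested for each inhibitor, 0 passed by camera, by fry or with an estimated correlation. At this depth the simulated test recovered 8 of 93 genes that changed 4-fold and 0 of 97 that changed 2-fold, so these zeros do not show an unchanged response. The difference test is not stable to the counting: total read counts called 1369 and 769 genes, and keeping every gene with at least 1 UMI called 233 and 91.

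The reporters asked which transcription factor activities the inhibitors moved over all conditions. The NF-kB reporter NFkB_1 fell by 0.82 ± 0.11 on the log2 scale under dCA and fell by 0.78 ± 0.11 under BRD-6989, lower in 12 of 12 conditions for both (adjusted p = 1.82e-11 and 8.07e-11). The interferon-beta promoter reporter IFNB1_44 fell by 0.35 ± 0.05 and fell by 0.42 ± 0.05. IRF1_55 fell by 0.20 ± 0.04 and fell by 0.31 ± 0.04. Under dCA and BRD-6989 in turn, SRF_11 rose by 0.34 ± 0.04 and 0.26 ± 0.04, AP1_33 by 0.40 ± 0.06 and 0.37 ± 0.06, and NRF2_4 by 0.22 ± 0.04 and 0.41 ± 0.04. SREBP_29 rose by 0.23 ± 0.04 and 0.27 ± 0.04, and TFEB_28 by 0.25 ± 0.03 and 0.26 ± 0.03. Each of these changes passed the threshold. Of 58 reporters, 20 passed under dCA (9 higher, 11 lower) and 22 under BRD-6989 (11 higher, 11 lower). These are changes relative to the panel, which sets the balance of directions. Scaled by the UMI total without Rn45s, the median over the panel moved to 0.15 and -0.25, and 38 and 49 passed, 92.1% and 4.08% of them higher. Under this scaling NFkB_1 stood at -0.65 under dCA, and TFEB_28 (0.03) and SREBP_29 (0.05) lost their calls under BRD-6989. Library totals gave 39 and 38, with 89.7% and 84.2% higher and panel medians of 0.11 and 0.12. A fit without the replicate block gave 7 and 11. Among the calls it ended were those of NFkB_1 (adjusted p = 0.102), IFNB1_44 (0.259) and TFEB_28 (0.0552) under dCA, and of IFNB1_44 (0.158), IRF1_55 (0.0740) and NRF2_4 (0.0904) under BRD-6989.

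Between stimuli in DMSO, 14 of 58 reporters differed. Relative to the panel, NFkB_1 rose with each of the 11 stimuli, from 1.38 ± 0.23 with SeV to 2.35 ± 0.23 with MDP. Its mean count from 60 min on rose 15.7-fold with MDP and 29.0-fold with LPS. IFNB1_44 rose by 2.23 ± 0.26 with LPS, 2.05 ± 0.27 with Poly(I:C) and 1.24 ± 0.30 with SeV, and stood at 0.56 ± 0.32 with TDB. ISRE_54 rose with Poly(I:C) (0.83 ± 0.25), SeV (0.76 ± 0.26), LPS (0.69 ± 0.25) and MDP_LPS (0.68 ± 0.25). Relative to the panel, IRF3.7_45 fell with Pam3cys (-0.82 ± 0.19), CpG, R848 and FLA, and NRF2_4 by most with LPS (-2.09 ± 0.26). Counts of IRF3.7_45 with these stimuli lay above NoStim at each time from 60 min on, at 120 min 66, 69, 94 and 77 against 20. Counts of NRF2_4 with LPS went both ways, 61 against 42 in NoStim at 120 min and 25 against 34 at 150 min. The adjusted p of the test across stimuli was 2.24e-26 for IFNB1_44, 2.42e-18 for NFkB_1, 7.34e-16 for IRF3.7_45, 2.21e-09 for ISRE_54 and 1.91e-08 for NRF2_4. The whole panel rose with stimulation, 7.40-fold with LPS and 2.32-fold with TDB. The reporter named for a minimal promoter, minP, rose 7.00-fold with LPS. A fall or an order of stimuli relative to the panel therefore need not hold for counts. In counts, too, NFkB_1 rose least with SeV, 6.16-fold.

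**Figure D3:**
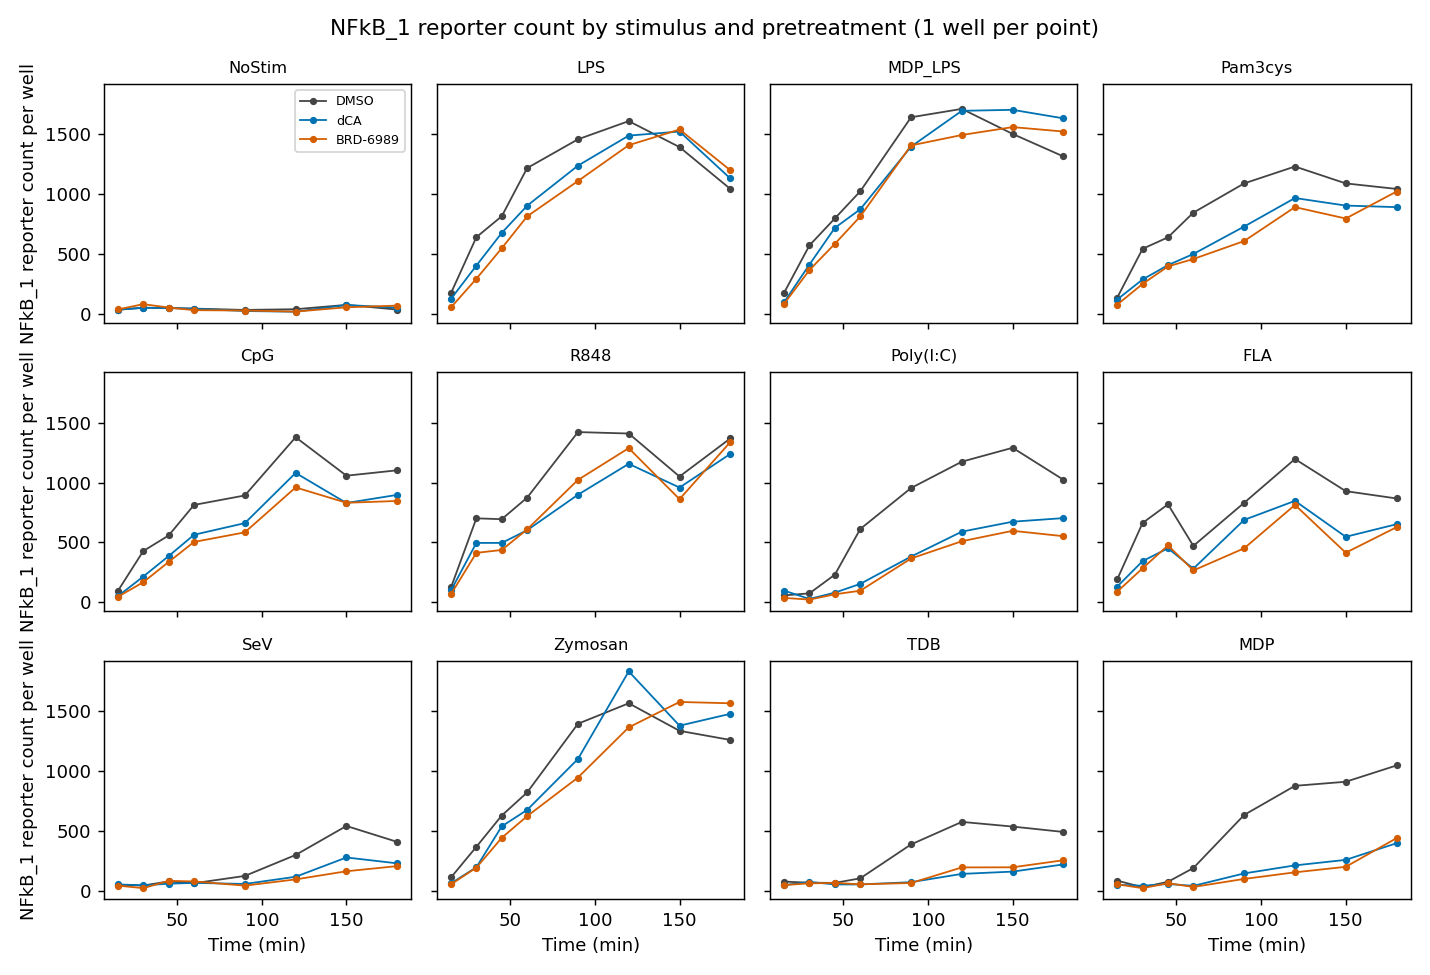
NFkB_1 reporter count per well (vertical axis) by time in minutes (horizontal axis) for 12 stimulus conditions, with 1 well per point and a line for each pretreatment. With LPS the lines lie together, at means of 1345, 1257 and 1215 counts from 60 min in DMSO, dCA and BRD-6989, and with MDP they part, at 730, 210 and 184.

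The effect of the inhibitors on NFkB_1 differed between stimuli. From 60 min on, NFkB_1 took 27.1% of the panel with MDP in DMSO, 10.1% in dCA and 10.2% in BRD-6989, and with TDB 23.1%, 7.78% and 9.35%. With LPS the shares were 23.3%, 21.1% and 20.6%, and without a stimulus 5.96%, 3.33% and 3.75%. Mean NFkB_1 counts without a stimulus lay close together, at 46.4, 43.2 and 41.4, while mean panel totals were 779, 1297 and 1103. The lower NoStim shares thus came mostly from a larger panel, which also enters each difference from NoStim below. The test of any difference between conditions gave an adjusted p of 6.05e-07 for dCA and 5.30e-06 for BRD-6989 over 58 reporters. Against the effect in NoStim wells, the change with MDP was -0.81 ± 0.34 under dCA and -1.01 ± 0.34 under BRD-6989, with TDB -0.84 ± 0.34 and -0.77 ± 0.34, with Poly(I:C) 0.08 ± 0.33 and -0.14 ± 0.34, with SeV -0.12 ± 0.34 and -0.30 ± 0.34, and with LPS 0.68 ± 0.33 and 0.45 ± 0.33. None of these single differences passed the adjustment.

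The targets of the inhibitors and Il10 lay near the limit of the counts. Cdk8 (chromosome 5, 146230795 to 146302874) had 70 UMI over 96 DMSO wells, 111 in dCA and 114 in BRD-6989, and the related kinase gene Cdk19 had 85, 67 and 65. Their cyclin gene Ccnc had 59, 66 and 121. Of the other module genes, Med12 at -0.59 ± 0.25 under dCA (adjusted p = 0.107, lower in 9 of 12 conditions) missed the threshold and fell by 1.02 ± 0.26 under BRD-6989, and Med13 stood at -0.07 ± 0.32 and 0.08 ± 0.31. Il10 (chromosome 1, 131019845 to 131024970) had 78 UMI in DMSO, 52 in dCA and 75 in BRD-6989, or 22.0, 14.4 and 17.3 per 1e6 UMI other than Rn45s, with 95% Poisson intervals of 17.4 to 27.5, 10.8 to 18.9 and 13.6 to 21.7. Il6 had 19, 15 and 38. Il10 counts were highest with MDP_LPS (24, 15 and 27), with R848 they were 15, 5 and 19, and NoStim wells had 0, 1 and 1. Cdk8, Cdk19, Ccnc, Il10 and Il6 did not pass the count filter over all conditions. In edgeR with every gene that had at least 1 UMI, none of these 5 passed the threshold. Il10 stood at -0.50 ± 0.51 under dCA (adjusted p = 0.790) and -0.54 ± 0.49 under BRD-6989 (0.726), and Il6 at -0.22 ± 0.89 (0.979) and 0.51 ± 0.87 (0.849). With these errors a difference in either gene is neither shown nor excluded.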

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

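The tests of plate, of the NFkB_1 pattern and of well depth were chosen after the results they measure were seen; the tests of the Rn45s share, of the shared DMSO libraries and of random regroupings were not. Of 75 groups of wells looked at for a well that stood apart, 4 had one, and chance gives about 1 in 20. The UMI total of the DMSO Pam3cys well at 15 min was 115242, against 52357 to 81455 at the other times. That of the DMSO Poly(I:C) well at 30 min was 123855, against 66476 to 91050. Rn45s took 34.0% of the UMI in the DMSO R848 well at 60 min, against 47.4% to 57.5%. In the dCA Pam3cys well at 150 min it took 35.3%, against 49.5% to 54.9%.

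The inhibitor effect on the NFkB_1 reporter differed between stimuli, with an adjusted p of 6.05e-07 for dCA and 5.30e-06 for BRD-6989 (test of any difference). Against the effect in NoStim wells, the change under dCA and BRD-6989 was -0.81 ± 0.34 and -1.01 ± 0.34 on the log2 scale with MDP and -0.84 ± 0.34 and -0.77 ± 0.34 with TDB, and none of these passed the adjustment. Poly(I:C) and SeV lay within 1 SE of 0 on this measure, which is relative to the panel. In counts, NFkB_1 rose over NoStim 21.8-fold with Poly(I:C) in DMSO, 11.6-fold in dCA and 10.3-fold in BRD-6989. With SeV it rose 6.16-, 3.44- and 2.80-fold, and with LPS 29.0-, 29.1- and 29.3-fold. The whole panel also rose less with Poly(I:C) under the inhibitors, 2.50- and 2.52-fold against 5.81-fold in DMSO. An offset by the same factor in all wells of a plate would shift every stimulus alike on the log2 scale. The test of any difference argues against such an offset. It is also the test that flagged the pattern, so it is no separate evidence, and it does not bear on other differences between plates. LPS carried over from a neighbouring plate column could raise NFkB_1 in DMSO. For MDP, TDB and Poly(I:C) carry-over cannot be told apart from the stimulus, since their columns lie at most 1 column from one with LPS. SeV wells, with no LPS column beside them, decide nothing: they stood at -0.77 ± 0.25 relative to LPS (mean of both inhibitors) but at -0.21 ± 0.29 relative to NoStim, so the gap can come from LPS. A weaker NF-kB response to MDP and TDB under CDK8 inhibition stays open as an untested hypothesis, which repeat plates with the stimuli in other columns would test.

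Interferon response genes were lower under both inhibitors. With the Rn45s share of each library as a covariate the median of the 46 genes was -0.37 for dCA (-0.36 without) and -0.83 for BRD-6989 (-1.02 without), which argues against that share as the whole cause, although the fitted falls past the threshold went from 18 to 8 and from 34 to 9 as fewer genes passed overall (604 and 191). Whether sharing the DMSO libraries adds to the falls of these 46 genes is not decided. With different conditions for each inhibitor, 6 each, the covariance of the changes was 0.164, but over all 5712 genes. It was not measured for the interferon list, and the DMSO plate stayed common to both effects. The highest simulated value of 0.0023 is no benchmark, since the noise of the DMSO libraries could not enter the simulation. Each pretreatment had 1 plate, so plate and inhibitor cannot be told apart for any effect of an inhibitor. An effect of both inhibitors on interferon genes is therefore a hypothesis and no more.

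The whole reporter panel rose with stimulation in DMSO, with a median of 5.55-fold over 11 stimuli. The gene UMI total of the same wells changed by a median of 1.03-fold, from 0.743-fold with LPS to 1.23-fold with FLA. This argues against the depth of the gene counts as the cause. It does not measure the depth of the reporter reads, so that stays open. No biological explanation was tested.

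Random regroupings of the same libraries or wells were counted for each comparison. Over all conditions 1 of 100, the real grouping, gave as many genes for dCA (1023, highest other 1), BRD-6989 (1195, highest other 26) and dCA against BRD-6989 (198, highest other 1), and in unstimulated wells also 1 of 100 (58, highest other 12, and 66, highest other 21). Another set of draws, with the libraries in another order, reached a highest other number many times higher for dCA, a lower one for BRD-6989 and a higher one for gene lists, all below the real ones, so these highest numbers vary between draws. Among 61 groupings, only the real one reached its number for LPS (61, highest other 2), MDP_LPS (61, highest 1), Pam3cys (26, highest 1), CpG (15, highest 2), R848 (32, highest 2), Poly(I:C) (31, highest 0), FLA (12, highest 0), Zymosan (32, highest 0), MDP (4, highest 1) and SeV (2, highest 1). For TDB 3 of 61 reached 1 gene, so that call barely stands out. Reporters gave 1 of 100 for dCA (20, highest other 1), BRD-6989 (22, highest 4) and stimuli (14, highest 2). Gene lists gave 1 of 100 (21, highest other 11), with at least 1 list called in 56 of the 99 others. For the effects on the response all 9 of 9 groupings reached the real number of 0, and the highest other was 2, so those tests say nothing against chance.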

How the results depend on the processing

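Leaving out Rn45s, leaving out shallow wells in the stimulus tests and scaling reporters by UMI were chosen after seeing the data. No DMSO well was shallow enough to be left out of the stimulus tests. The values of that alternative, counted below as kept, therefore repeat the main ones. Depth limits the single-well tests: simulated 4-fold changes in unstimulated wells were recovered for 3 of 64 genes with a mean of 1 to 5 UMI and 6 of 6 with at least 20. Over all alternatives, 5516 values of named genes kept their direction and side of the threshold, 337 lost their call, 56 gained one and 160 changed sign, none of them a called value; for gene lists these numbers were 96, 7, 7 and 4, and for reporters 237, 9, 0 and 0. Where no cause is named, the cause was not tested. The limma alternatives on normalized reporter values were not run, since those values are the counts.

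The stricter filter, which tests fewer genes, called 322 genes for dCA and 325 for BRD-6989 and raised the correlation of their effects to 0.898. Wells of 60 min and later, fewer counts, called 779 genes for BRD-6989 and 82 between inhibitors. Total read counts gave 84 between inhibitors, 28 and 30 in unstimulated wells, 30 for LPS, 28 for MDP_LPS, 17 for Pam3cys, 9 for CpG, 15 for R848, 17 for Poly(I:C), 19 for Zymosan, 2 for TDB, 1369 and 769 for the difference tests of dCA and BRD-6989, and a correlation of 0.688. Without the replicate block the counts were 75 between inhibitors, 9 for CpG, 1 for SeV, 0 for TDB, and 7 and 11 reporters for dCA and BRD-6989. The DESeq2 Wald test gave 88 for dCA in unstimulated wells, 28 for CpG, 24 for FLA, 8 for TDB and 9 for MDP. With all 8 times FLA had 22, and SeV, TDB and MDP 0. TDB had 3 with DESeq2 size factors, 2 with every gene that had at least 1 UMI and 3 without Rn45s. Every gene with at least 1 UMI gave 233 and 91 in the difference tests and 1 for the BRD-6989 effect on the response. Reporters past the threshold were 39 and 38 with library totals and 38 and 49 scaled by UMI. Leaving out 1 condition or time gave 36 to 63 for MDP_LPS, 15 to 25 for Pam3cys, 9 to 18 for CpG, 20 to 35 for R848, 16 to 27 for Poly(I:C), 7 to 16 for FLA, 0 to 4 for SeV, 0 to 5 for TDB, 2 to 4 for MDP and 0 to 1 for the BRD-6989 effect on the response. List tests that changed direction with total read counts had adjusted p of 0.587 and 0.420 (interleukin-10 axis, dCA and BRD-6989), 0.866 (heat shock, dCA) and 0.950 (TGF-beta, BRD-6989).

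Log2 values that changed sign all belong to genes that were not called. Without the replicate block, the values were, for dCA against BRD-6989 over all conditions Cxcl10 -0.059 and Nfkbiz -0.019, for dCA in unstimulated wells Med12 0.42, and for BRD-6989 in unstimulated wells Med12 0.60. Under LPS Med12 0.21, under MDP_LPS Med13 -0.23, and under CpG Med13 -0.26. Under SeV Tnf -0.012 and Egr1 -0.071, under MDP Med13 -0.050, and for the BRD-6989 effect on the response Nfkbiz 0.14 and Jun 0.13. With wells as units, the values were, for dCA against BRD-6989 over all conditions Nfkbiz -0.084. With the stricter filter, the values were, for dCA against BRD-6989 over all conditions Nfkbiz -0.023. With total read counts, the values were, for BRD-6989 in unstimulated wells Nfkbiz 0.074, under LPS Med13 0.40, and under MDP_LPS Jun 0.58. Under Pam3cys Il12b 0.75, under CpG Fos -2.31, and under R848 Fos -1.17. Under SeV Tnf -0.32 and Med13 0.18, under Zymosan Egr1 0.43 and Med12 -0.067, and under TDB Il10 0.028. Under MDP Tnf 0.17 and Med12 -0.39, for the dCA effect on the response Tnf 0.31, Fos 0.85 and Jun -0.41, and for the BRD-6989 effect on the response Cxcl10 -0.085 and Med13 -0.040. With all 8 times, the values were, under LPS Med13 1.41, under MDP_LPS Jun 0.38, and under Poly(I:C) Nfkbiz -0.031. Under FLA Il12b 0.84, Fos 0.96 and Egr1 2.60, under SeV Tnf -0.68, and under Zymosan Fos 0.61 and Egr1 1.69. Under TDB Il1b 0.71, Ifit1 -1.05 and Med13 0.64, under MDP Ifit1 -0.58, Fos 0.34 and Egr1 0.59, and for the dCA effect on the response Tnf 0.48 and Cxcl10 -0.060. For the BRD-6989 effect on the response Il1b -0.31, Ifit1 0.56, Nfkbiz 0.48, Jun 0.067, Med12 -1.80 and Med13 -0.29. With DESeq2 size factors, the values were, under Poly(I:C) Med12 -0.076, and under SeV Egr1 -0.022. With the DESeq2 Wald test, the values were, under Poly(I:C) Med12 -0.14. With every gene that had at least 1 UMI, the values were, under SeV Egr1 -0.034, for the dCA effect on the response Tnf 0.045, and for the BRD-6989 effect on the response Jun 0.011. Without Rn45s, the values were, under SeV Egr1 -0.020.

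Leaving out 1 condition or time gave these ranges across 0. For dCA over all conditions Med13 -0.40 to 0.11. For BRD-6989 over all conditions Med13 -0.024 to 0.27. For dCA against BRD-6989 over all conditions Nfkbiz -0.044 to 0.094. For dCA in unstimulated wells Med12 -0.59 to 0.41. For BRD-6989 in unstimulated wells Nfkbiz -0.87 to 0.090 and Cdk8 -1.20 to 0.16. Under LPS Fos -0.38 to 2.17, Jun -0.86 to 0.018, Egr1 -0.99 to 3.62, Med12 -2.69 to 0.29 and Med13 -0.78 to 0.98. Under MDP_LPS Jun -0.81 to 0.74 and Med13 -0.48 to 1.44. Under Pam3cys Il12b -2.13 to 0.77 and Med12 -0.90 to 0.21. Under CpG Ifit1 -0.50 to 1.39, Fos -0.47 to 1.06, Egr1 -0.52 to 4.44, Med12 -0.014 to 1.67 and Med13 -1.14 to 1.70. Under R848 Fos -0.78 to 2.06 and Med13 -0.54 to 1.81. Under Poly(I:C) Il10 -0.021 to 2.93, Il12b -0.63 to 1.22, Med12 -0.16 to 0.84 and Med13 -0.087 to 2.19. Under FLA Il12b -1.72 to 0.031 and Egr1 -1.33 to 3.05. Under SeV Il10 -0.061 to 1.44, Tnf -0.33 to 0.49, Egr1 -0.37 to 2.57 and Med13 -1.26 to 0.55. Under Zymosan Fos -3.17 to 0.18, Egr1 -1.17 to 3.14, Med12 -2.01 to 1.22 and Med13 -0.95 to 0.58. Under TDB Tnf -1.09 to 0.31, Ifit1 -0.36 to 0.70, Fos -0.54 to 1.32, Jun -1.47 to 0.047 and Med12 -0.11 to 2.89. Under MDP Tnf -0.50 to 0.034, Il1b -2.03 to 0.73, Fos -0.90 to 0.26, Egr1 -1.13 to 3.20, Med12 -0.47 to 1.11 and Med13 -0.38 to 1.79. For the dCA effect on the response Tnf -0.56 to 0.32, Il1b -0.036 to 1.89, Cxcl10 -0.19 to 0.94, Jun -0.010 to 0.43, Egr1 -1.65 to 2.37, Ccnc -1.34 to 0.48, Med12 -2.04 to 0.17 and Med13 -1.19 to 0.14. For the BRD-6989 effect on the response Cxcl10 -0.051 to 0.67, Ifit1 -1.23 to 0.68, Nfkbiz -1.72 to 0.54, Jun -0.24 to 0.43, Egr1 -0.94 to 2.84 and Med13 -0.95 to 1.36.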

Other observations

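The values in this part come from gene lists fixed in advance; no test in it was chosen after the result was seen, and no explanation was tested. The 10 genes listed as osteoclast markers summed to 284 UMI in DMSO, 967 in dCA and 1266 in BRD-6989, a sum that a few members can carry and that was not tested as a list. Of the 3 that could be tested, the proton pump subunit gene Atp6v0d2 rose by 2.31 ± 0.25 under dCA and 2.35 ± 0.25 under BRD-6989 on the log2 scale, the integrin gene Itgb3 by 3.04 ± 0.52 and 2.87 ± 0.51, and the metalloprotease gene Mmp9 by 1.77 ± 0.41 and 2.16 ± 0.40, in 11 or 12 of the 12 conditions each. MHC class II genes had 320, 122 and 172 UMI and were too low to test.

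Markers of other cell types were scarce in DMSO, dCA and BRD-6989. Neutrophil genes had 259, 214 and 233 UMI, B cell genes 8, 6 and 8, T and NK cell genes 31, 37 and 42, erythroid genes 4, 19 and 55, and mast cell and basophil genes 1, 0 and 0. Fibroblast and stroma genes had 260, 261 and 274. Dendritic cell genes had 1015, 1008 and 883, and Bst2, the member that could be tested and one that interferon induces, fell by 0.53 ± 0.12 under BRD-6989. The 7 genes of the Mediator kinase module summed to 1669, 1341 and 1734 UMI, and 14 Wnt targets to 4268, 3696 and 4409. Mitochondrially encoded transcripts are not in the deposited tables.

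Other lists were tested and not called by camera, with adjusted p from 0.0851 to 0.877: the interleukin-10 axis, heat shock, p53 targets, alternative activation, TGF-beta and SMAD targets, and the STAT5 and M-CSF response under both inhibitors, the unfolded protein response and macrophage identity under dCA, and immediate early genes, lysosome and oxidative phosphorylation under BRD-6989. In the interleukin-10 axis list, 2 of 11 genes rose and 3 fell under dCA and 4 rose and 4 fell under BRD-6989, where the median of -0.05 and the test differ in sign. The lowest camera adjusted p among these was that of immediate early genes under BRD-6989, where 5 of 22 rose and 8 fell (median -0.27). By fry some of these lists passed, with adjusted p from 2.9e-10 to 0.0151. They were lysosome, immediate early genes and the STAT5 and M-CSF response under BRD-6989. Under dCA they were macrophage identity, the unfolded protein response and TGF-beta and SMAD targets. The other lists not called by camera did not pass by fry either.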
